A study of Mus musculus with 6 samples.

How the data were processed

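RNA was measured on 6 arrays, 1 per sample, from proprioceptive sensory neurons of mouse dorsal root ganglia collected between postnatal days 7 and 10. Per the labels' protocols, neurons supplying muscle spindles (MS) and neurons supplying Golgi tendon organs (GTO) carried different combinations of fluorescent proteins, were separated by fluorescence-activated cell sorting, and were pooled over several sorts. The 3 MS samples held about 1250 neurons each and the 3 GTO samples about 725 each. Per the labels, the RNA was amplified before biotin labelling. The labels call the samples of a group biological replicates, so the p-values measure the spread between pools of neurons. The animals behind each pool were not given in the sources used here.

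The deposited table holds log2 values for 45101 probe sets. GCRMA and Partek are named in the submitters' processing notes, with no version. GCRMA is a method that corrects background by probe sequence and normalizes arrays by quantiles before probes are summarised. The log2 scale was checked against the authors' deposited list: 2 to the power of the difference between group means gave the deposited fold of each listed probe set, with a largest relative deviation of 2.1e-05. The authors also deposited a list of 626 probe sets with a p-value and a linear fold ratio (MS over GTO) for each, selected per the file headers at a minimum of 5-fold and a p-value below 0.08. The columns of F scores and sums of squares deposited by the authors were not used further. The genome build and the array annotation were not given in the sources used here, and no coordinates are printed.

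Only the deposited list pairs probe sets with genes. It gives 1 symbol for 591 probe sets, several for 17 and none for 18, which makes 570 distinct genes. Symbols were updated through the Entrez identifier with a RefSeq gene table for the assembly GRCm38.p6; 584 probe sets matched and 38 symbols changed. In 1 cell a symbol had been turned into a number by a spreadsheet and was read as Septin11. Probe sets with several symbols name no gene here. Genes of probe sets outside the list, including all that were higher in GTO, cannot be named here, so such probe sets are counted, with values given for a pair of them.

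The 64 control probe sets were left out of the tests, which left 45037. Of these, the 16256 with a log2 value of at least 4 on at least 3 arrays were tested for a difference between 3 MS and 3 GTO arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without an intensity trend, two-sided, no covariate). P-values were adjusted by the Benjamini-Hochberg method over these probe sets, with a threshold of 0.05. A looser count took a difference of at least 2-fold and an unadjusted p under 0.05. The rule of the deposited list was also applied in both directions to all probe sets, with the equal-variance test on log2 values. Where the lower group lay under log2 4 on all its arrays, the fold is given as a lower bound, the mean of the higher group against the level of log2 4. Apart from the fitted differences of the 3 genes past the threshold, a plain log2 difference is printed for named genes that reached log2 4 on at least 1 GTO array, and includes the values of any GTO array below it. Bacterial spike-in control probe sets, 27 in number, read between 1.86 and 2.89 and mark the background. Group comparisons of array measures used exact permutation tests. Their smallest possible p with 3 against 3 arrays is 0.1.

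The model was tested on simulated data with the spread of the 16256 probe sets of the MS and GTO comparison and 50 changed probe sets of each size. It called 0 of those with a log2 difference of 1, 0 at 2, 15 (30.0%) at 4 and 30 (60.0%) at 6, with 1 false call. The simulated values varied independently, with the same spread in both groups and no differences in signal between arrays. These counts therefore do not give the error rate on the real arrays. The number of arrays limits the precision.

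Named genes followed a rule fixed before the data were examined. It took the 12 genes with the largest difference in each direction among probe sets past the threshold, with no overlap between groups and 1 symbol, filled up by the smallest unadjusted p among differences of at least 2-fold. It added every member of the proprioceptor and MS or GTO subclass lists and Egr3, up to 4 members with the smallest p of each other list, and the 5 probe sets with the largest deposited fold. The 33 lists, with 499 genes, covered cell types of the ganglion and functions of sensory neurons. Tests of these lists as sets (camera and fry) were not run. Every gene that can be named was selected for being higher in MS, which leaves no background for such a test. The lists are therefore given as counts of members on the deposited list. Some genes that the rule or a later choice took are not reported here.

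The alternatives were the replicate number as a block, no filter and a filter at log2 6, quantile normalization and median centring of the deposited values, a floor at log2 4, array weights, an intensity trend with robust variance, the ordinary statistic without moderation, and leaving out each array. Chosen after the data had been seen were leaving out GTO arrays 2 and 3 together and a block for a split of the arrays. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.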

Results

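The dataset compares the RNA of both classes of proprioceptive sensory neurons, which report muscle length (MS, ending on muscle spindles) and muscle tension (GTO, ending on Golgi tendon organs). Sorted MS neurons made up 3 samples and sorted GTO neurons 3 samples, each on 1 array of 45101 probe sets. Signal differed between the arrays. The upper quartile of the log2 values was 6.86, 6.86 and 6.78 on MS arrays 1, 2 and 3, and 6.67, 6.20 and 5.55 on GTO arrays 1, 2 and 3. The group means were 6.83 ± 0.04 for MS and 6.14 ± 0.56 for GTO (SD, n = 3, exact permutation p = 0.1, the smallest possible, adjusted p = 0.225 over 9 array measures). The share of probe sets under log2 4 was 62.5% ± 0.374 in MS and 65.9% ± 1.57 in GTO (SD, n = 3, exact permutation p = 0.1). The 3' probe set of beta-actin, 1 of the control probe sets, read 13.24 ± 0.03 in MS and 12.63 ± 0.33 in GTO (SD, n = 3, exact permutation p = 0.1), while that of Gapdh read 14.66 ± 0.13 in MS and 14.82 ± 0.21 in GTO (SD, n = 3, exact permutation p = 0.4). The difference between the 3' and middle Gapdh probe sets, a sign of RNA length, was 2.02 ± 1.35 in MS and 3.78 ± 0.41 in GTO (log2, SD, n = 3, exact permutation p = 0.2). The other 3 such differences lay closer: 3.13 and 3.55 between the 3' and 5' Gapdh probe sets, 0.57 and 0.50 for beta-actin, and 1.24 and 1.55 between the 3' and middle beta-actin probe sets in MS and GTO (exact permutation p = 0.6, 0.7 and 0.8). Correlations across probe sets, which are not independent replicates, were 0.927 to 0.942 between MS arrays, 0.85 to 0.892 between GTO arrays and 0.858 to 0.943 between an MS and a GTO array. The highest was between MS array 3 and GTO array 1.

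**Figure D1:**
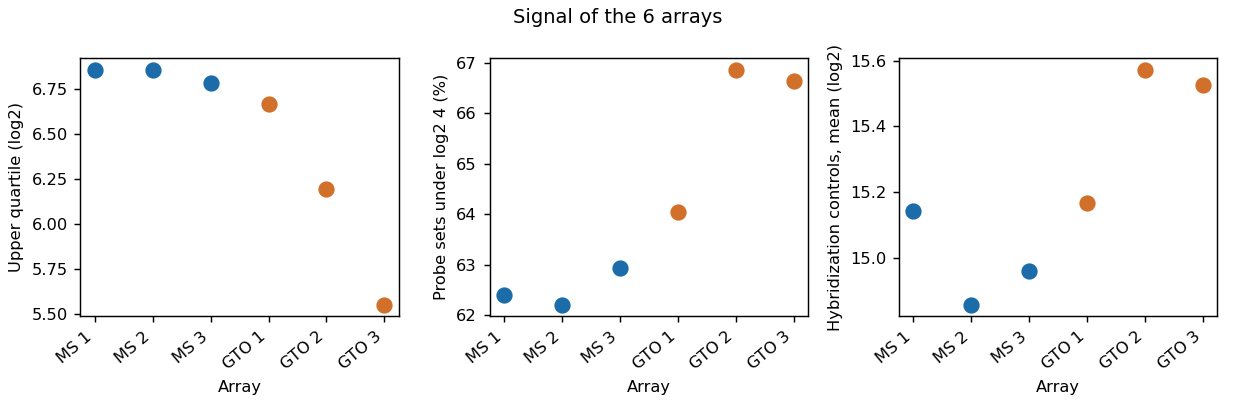
Signal of each array (MS blue, GTO orange; 1 point per array): upper quartile of the log2 values, percentage of probe sets under log2 4, and mean log2 value of the 18 hybridization control probe sets. GTO arrays 2 and 3 have upper quartiles of 6.20 and 5.55, below the 6.78 to 6.86 of the MS arrays.

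The main question was which transcripts differ between MS and GTO neurons. Probe sets of 3 genes were higher in MS neurons past the threshold, and these 3 probe sets lay under log2 4 on every GTO array. Neurons per sample and array signal were also lower in GTO, so neither can be told apart from the neuron class here. Other probe sets of Pcmtd1 and Pik3c3 could not be named here without the array annotation. Pcmtd1, which encodes a protein with an isoaspartyl methyltransferase domain, measured 9.91 ± 0.54 in MS and 2.84 ± 0.20 in GTO (log2, SD, n = 3), at least 60.0-fold higher (limma adjusted p = 0.0356). Ctnna1, alpha-catenin, which links cadherins to actin, measured 9.67 ± 0.53 and 2.93 ± 0.30 with the probe set past the threshold, which read at least 51.1-fold higher (limma adjusted p = 0.0362). A second probe set of Ctnna1 measured 8.68 ± 0.03 and 3.79 ± 0.57, with a smaller deposited fold of 29.7, and did not pass (limma adjusted p = 0.0597). Pik3c3, a lipid kinase of autophagy and endosomal sorting, measured 9.31 ± 0.25 and 3.25 ± 0.08, at least 39.8-fold higher (limma adjusted p = 0.0356). The fitted log2 differences of the deposited values, in which GTO lies near background, were 7.07 ± 0.46, 6.74 ± 0.47 and 6.06 ± 0.39 (SE) for Pcmtd1, Ctnna1 and Pik3c3. Each was higher in 3 of 3 MS arrays than on any GTO array. No probe set passed in limma when any 1 of the 6 arrays was left out, with 796 to 1786 at an unadjusted p under 0.05 and at least 2-fold. All 3 calls also ended under median centring (limma adjusted p = 0.0566) and with the floor at log2 4 (limma adjusted p = 0.0569). They ended as well with the intensity trend (limma adjusted p = 0.218) and with the replicate number as a block (limma adjusted p = 0.418). Those of Pcmtd1 and Ctnna1 ended with the ordinary statistic (adjusted p = 0.0767). The range was 0.0069 to 0.418 over the alternatives with more than 1 array in each group.

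The next genes by p had larger values on every MS array than on any GTO array and did not pass. Ifi35, an interferon-induced protein, measured 7.61 ± 0.49 in MS and 2.49 ± 0.09 in GTO, and Nfe2l2, a transcription factor of the oxidative stress response, 8.17 ± 0.61 and 2.81 ± 0.07 (SD, n = 3, limma adjusted p = 0.0597 for both). The orphan receptor gene Gpr165, the lysosomal mannosidase gene Manba and the pyruvate dehydrogenase kinase gene Pdk2 read at least 8.29-fold, 8.81-fold and 19.8-fold higher in MS at the same adjusted p. Ahnak, a very large scaffold protein, had the largest deposited fold and measured 9.05 ± 1.37 in MS and 1.90 ± 0.14 in GTO (SD, n = 3), at least 33.1-fold apart (limma adjusted p = 0.0820). Polr2a, the largest subunit of RNA polymerase II, Lrrk2, a kinase of vesicle traffic, and Tub, the tubby protein, read at least 6.59-fold, 10.4-fold and 8.23-fold higher in MS (limma adjusted p = 0.0820). Selenok, a selenoprotein of the endoplasmic reticulum, read at least 30.7-fold higher in MS (limma adjusted p = 0.0820), and a probe set with no symbol at least 26.1-fold (limma adjusted p = 0.0597). All of these were under log2 4 on the 3 GTO arrays.

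No probe set was higher in GTO neurons past the threshold (limma, lowest adjusted p = 0.0597). At an unadjusted p under 0.05, 242 were higher in GTO, and 1 passed in that direction after adjustment with no filter on low values, with the filter at log2 6, with array weights and by the ordinary statistic. Of these, the probe set with the smallest unadjusted p, whose gene cannot be named here, measured 2.10 ± 0.03 in MS and 6.62 ± 0.13 in GTO, at least 6.16-fold higher in GTO (SD, n = 3, limma adjusted p = 0.0597, and 0.0028 to 0.521 over the alternatives). The next by p, also unnamed here, measured 2.66 ± 0.29 and 6.03 ± 0.54 (limma adjusted p = 0.127).

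**Figure D2:**
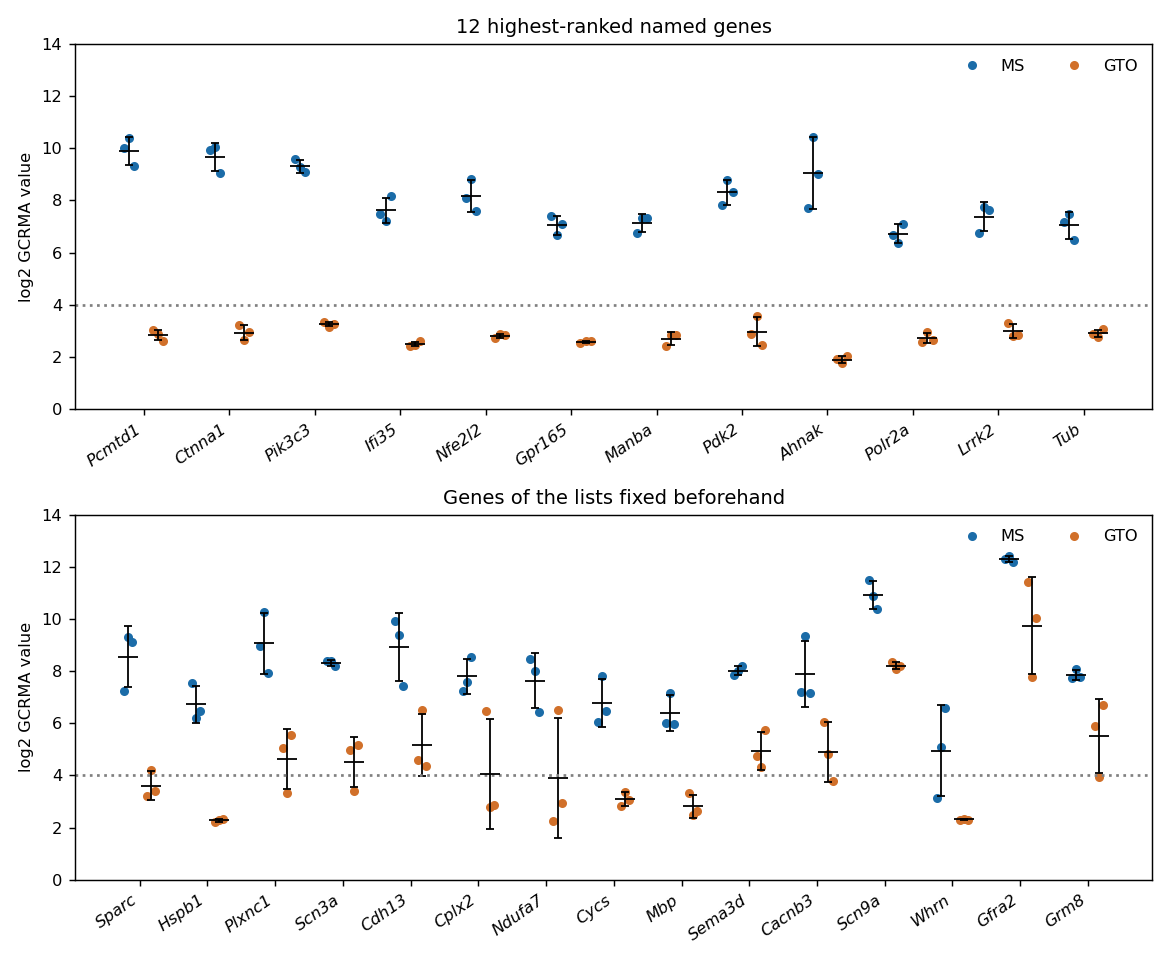
Log2 value on each array (points; MS blue, GTO orange) with the group mean and SD (bars, n = 3) for the 12 highest-ranked named genes and for genes of the lists fixed beforehand that are reported here, with 1 probe set per gene; the dotted line marks log2 4. The 12 genes in the upper panel lie under that line on all GTO arrays, while Gfra2 and Scn9a in the lower panel lie above it on all 6 arrays.

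Over the 16256 probe sets tested, 1295 differed by at least 2-fold at an unadjusted p under 0.05, against 812.8 such p-values expected by chance. Of these, 1053 were higher in MS (81.3%) and 242 in GTO. After quantile normalization of the deposited values the split was 700 to 638, and after median centring it was 742 to 472. The median log2 difference of all tested probe sets was 0.31 in favour of MS, and it shifted by -0.29 under quantile normalization and by -0.37 under centring. The count of 1295 fell to 820 without MS array 1 and to 796 without MS array 2.

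The authors' deposited list names genes enriched in MS neurons. Its 626 probe sets have deposited folds from 5.01 to 142 with a median of 9.34, and deposited p-values up to 0.0795. Applied to the deposited values, the rule of the list returned the same 626 probe sets, and 592 of them (94.6%) had no overlap between MS and GTO arrays. Chance gives 10% for probe sets not selected on these arrays, whereas the selection of the list itself favours separation. In the opposite direction the rule returned 63 probe sets, so that 90.9% of those passing were higher in MS. All 590 listed probe sets that passed the filter on low values were higher in MS, and 3 of them passed the adjusted threshold in limma. The list was chosen on these samples, so its direction is not independent evidence. Of the 626, 207 were under log2 4 on all 3 GTO arrays, 168 on 2 of them, 116 on 1 and 135 on 0. The mean of the listed probe sets was 7.87, 7.72 and 7.20 on MS arrays 1, 2 and 3, and 4.71, 4.01 and 3.82 on GTO arrays 1, 2 and 3. Without GTO arrays 2 and 3, which have the lowest upper quartiles, the rule gave 376 probe sets higher in MS and 519 higher in GTO. That test has 1 GTO array and takes its spread from the MS arrays alone. With GTO array 2 or 3 alone it gave 1118 against 672 and 1656 against 646, and with MS array 1, 2 or 3 alone against the GTO arrays 1346 against 134, 1150 against 107 and 787 against 30. Under quantile normalization it gave 400 and 128, and under median centring 429 and 125. The count higher in GTO was 40 without MS array 1 and 40 without MS array 2, 114 without MS array 3, and 124, 150 and 151 without GTO arrays 1, 2 and 3.

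**Figure D3:**
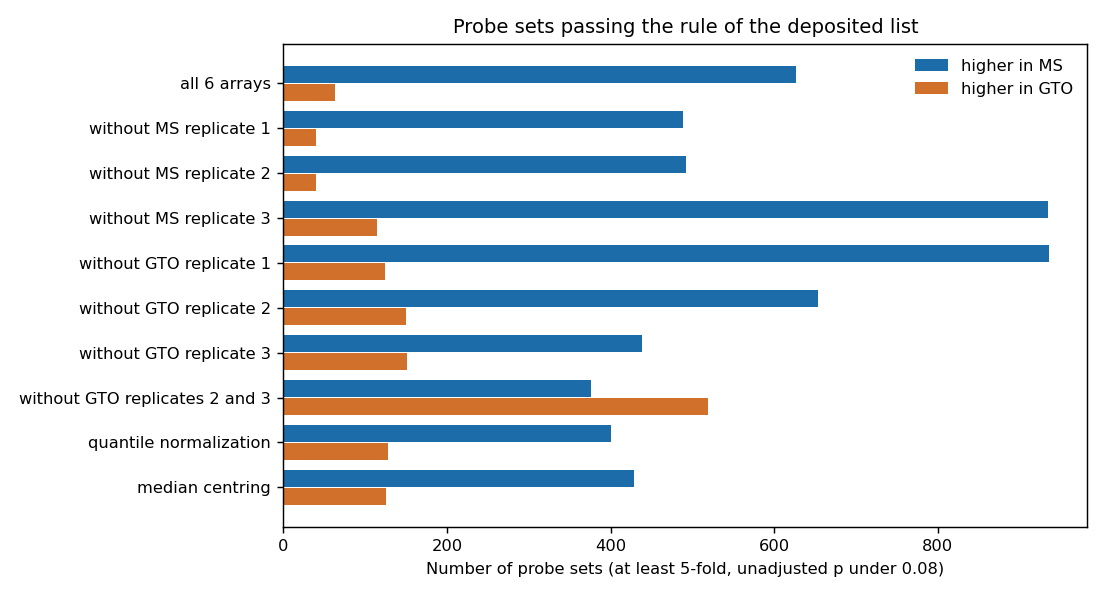
Number of probe sets with at least a 5-fold difference and an unadjusted p under 0.08 in each direction (bars; MS-higher blue, GTO-higher orange), with all 6 arrays, with arrays left out, and after 2 re-scalings. The counts are 626 and 63 with all arrays, and 376 and 519 without GTO replicates 2 and 3, where 1 GTO array is left and the spread comes from MS alone.

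Of the 499 genes in the lists fixed beforehand, 16 stood on the authors' deposited list, from 16 of the 33 lists. Over all probe sets tested, 590 of 16256 stood on it, a similar share. Without the array annotation no share per gene can be given, so the counts for each list do not show enrichment. None of the probe sets of the 16 genes passed adjusted over all tested probe sets in limma. Adjusted over the list alone, 16 of 16 tested probe sets had an adjusted p under the threshold, the highest being 0.0351. These genes could be named only because the authors had chosen them on the same samples, so the latter count is not independent evidence. Of the 8 proprioceptor markers, 1 was on the deposited list: Whrn, which encodes the scaffold protein whirlin, measured 4.96 ± 1.73 in MS and 2.31 ± 0.03 in GTO (SD, n = 3). It did not pass the filter on low values, and without that filter its limma adjusted p was 0.355. No MS or GTO subclass marker (Heg1, Nxph1, Pou4f3) stood on the list, nor did Egr3, a transcription factor of muscle spindle development whose gene was used in a label of the sort. The list holds only probe sets higher in MS, so a gene higher in GTO or alike in both could not stand on it. Absence from the list therefore says nothing of the levels of these genes.

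Among ion channels and synaptic genes, 2 of 13 sodium channel genes were on the list. Scn9a measured 10.92 ± 0.55 in MS and 8.21 ± 0.13 in GTO, the difference being 2.72 ± 0.46 (SE, n = 3, limma adjusted p = 0.165), and Scn3a measured 8.33 ± 0.11 and 4.51 ± 0.96 (SD, limma adjusted p = 0.142). The list also held 1 of 15 calcium channel genes (the auxiliary subunit Cacnb3, log2 difference 3.01). It held 1 of 22 glutamate receptor genes (Grm8, a metabotropic receptor, 2.35) and 1 of 28 release genes (Cplx2, a complexin, 3.75). None of these 3 passed (limma adjusted p = 0.459 to 0.525). Cplx2 read 6.48 on GTO array 1 against 2.81 and 2.86 on GTO arrays 2 and 3.

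Among guidance and adhesion genes, the list held 2 of 43 axon guidance genes and 1 of 20 cadherins. The secreted cue Sema3d measured 8.02 ± 0.17 in MS and 4.94 ± 0.72 in GTO (SD, n = 3, limma adjusted p = 0.160). The semaphorin receptor gene Plxnc1, also a marker of non-peptidergic nociceptors, had probe sets with log2 differences of 4.42 and 2.71 (limma adjusted p = 0.223 and 0.589). For the probe set with the smaller difference the groups overlapped, with 6.16 on GTO array 1 and 6.06 on MS array 3. Cdh13, a cadherin anchored by a lipid, differed by 3.76 (limma adjusted p = 0.338). Gfra2, a neurturin co-receptor counted with cutaneous mechanoreceptor markers and neurotrophic signalling, measured 12.30 ± 0.12 in MS and 9.75 ± 1.85 in GTO (SD, n = 3, limma adjusted p = 0.596). On GTO arrays 1, 2 and 3 Gfra2 read 11.43, 7.77 and 10.04.

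Markers of cells other than neurons were also on the list. Mbp, a myelin protein and 1 of 10 Schwann cell markers, measured 6.40 ± 0.68 in MS and 2.82 ± 0.44 in GTO (SD, n = 3, limma adjusted p = 0.133). Sparc, a matrix protein and 1 of 8 fibroblast markers, measured 8.56 ± 1.16 and 3.61 ± 0.55 (limma adjusted p = 0.127). No marker of satellite glia, macrophages, endothelium, pericytes, erythroid cells, skeletal muscle or the cell cycle stood on the list, which says nothing of their levels. Of 18 immediate early and stress genes, the small heat shock protein gene Hspb1 was listed, at least 6.61-fold higher in MS (limma adjusted p = 0.0854), and at least 1.22-fold by a second probe set that did not pass the filter on low values. Of 38 oxidative phosphorylation genes, Cycs (cytochrome c) and Ndufa7, a subunit of the first respiratory complex, were listed. Cycs read at least 6.85-fold higher in MS (limma adjusted p = 0.143), and Ndufa7 measured 7.63 ± 1.05 in MS and 3.90 ± 2.30 in GTO (SD, limma adjusted p = 0.534). For Ndufa7 the groups overlapped, with 6.53 on GTO array 2 and 6.44 on MS array 3. Lists with no member on the deposited list were those of general sensory neuron markers, C-fibre mechanoreceptors, peptidergic nociceptors, receptors for GABA and glycine, both groups of Hox genes, axon injury, ribosomal proteins, and the X inactivation and Y-linked genes.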

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

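The tests with single arrays, with control probe positions and with the split as a block were chosen after the data had been seen.

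Hybridization controls, which are added to the labelled material and enter no comparison of genes, were brighter on the GTO arrays. Their mean over 18 probe sets was 14.99 ± 0.14 in MS and 15.42 ± 0.22 in GTO (SD, n = 3, exact permutation p = 0.1, the smallest possible), a difference of 0.43 on the log2 scale with GTO higher. The highest mean, 15.57, was on GTO array 2, and GTO array 3 read 15.53, while GTO array 1 read 15.17 and the MS arrays 14.86 to 15.14.

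The first pattern is that differences of at least 5-fold lay mostly on the MS side, 626 probe sets against 63, a ratio of 9.94. Array-wide scaling may account for part of it, since the re-scalings lowered the ratio. They left 3.13 under quantile normalization (exact binomial 95% interval 2.55 to 3.84, with probe sets taken as independent) and 3.43 under median centring (2.81 to 4.22). Scaling as the whole cause would leave near-equal counts only if re-scaling restored signal lost to background, which it cannot. Of the 626 probe sets, 207 were under log2 4 on all GTO arrays. These ratios therefore do not decide whether scaling is the whole cause. The intervals do not include the spread between arrays. The looser count under quantile normalization was 700 against 638, which leaves scaling open for that count too. A lower signal on GTO arrays 2 and 3 also stays open, since the ratios with GTO array 1, 2 or 3 alone (0.72, 1.66 and 2.56) rest on the MS spread, as those with MS array 1, 2 or 3 alone (10.0, 10.7 and 26.2) rest on the GTO spread, and since probe sets chosen as higher in MS without a GTO array and an MS array differed between those held-out arrays by a median of 0.49 (range 0.14 to 0.59) for GTO array 1 and 1.01 (-0.04 to 1.11) for GTO array 2, which overlap, and 1.83 (0.66 to 2.01) for GTO array 3, while those chosen as higher in GTO differed in that direction by medians of 0.07, -0.36 and -0.34. The probe sets chosen in this way as higher in MS had median differences of 3.34 to 3.71 on the arrays that chose them. Between the held-out arrays, 14.8% to 46.3% of them stayed at least 5-fold and 47.1% to 76.9% kept their direction. Folds on the arrays used for the choice thus overstate those on other arrays. The number of neurons per sample, about 1250 for MS and 725 for GTO, follows the groups, so it and the biological difference between MS and GTO neurons both stay open and untested. The 10 splits of the 6 arrays are too few for a share under 0.05. By the rule of the list, 2 of the 10 gave as many probe sets (689 for MS against GTO, 729 at the highest other split). Past the adjusted threshold 2 gave as many (3 against 4), and in the looser count 2 (1295 against 1684). In the splits that mix the groups and keep GTO arrays 2 and 3 together, the rule gave 64, 46 and 41 probe sets higher on their side. On the other side, with GTO array 1, it gave 396, 271 and 329. The most lopsided remaining mixed split gave 529 against 200. In each mixed split the sides also differ in their number of MS arrays. Part of the lopsidedness thus goes with GTO arrays 2 and 3, but the splits share arrays, so its size cannot be told.

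The second pattern is that in all 3 counts the highest other split was the same, MS arrays 1 and 2 with GTO array 2 against MS array 3 with GTO arrays 1 and 3, although these counts overlap and no level for the highest of several splits without such a structure was computed. Within the sides of this split, which share no array, the MS minus GTO differences correlated across probe sets at r = 0.0774, and 471 probe sets were at least 5-fold higher in MS on both sides where independent lists would share 234.8, a ratio of 2.01; the difference between the sides, within MS and within GTO arrays, correlated at r = 0.174 with 299 shared against 110.4 (ratio 2.71), which the choice of this split for its high counts favours. With the split as a block 0 probe sets passed the adjusted threshold in limma (lowest adjusted p of the called genes 0.224, range over the alternatives 0.0069 to 0.521), yet the fitted log2 differences hardly moved, from 6.06 to 6.03 for Pik3c3, 7.07 to 6.91 for Pcmtd1 and 6.74 to 6.66 for Ctnna1, and the looser count was 1263, with 1065 higher in MS. The lost calls are therefore no evidence for the split as the whole source of the MS and GTO differences, which the low correlation leaves open. Unequal recovery of transcript length could underlie the split, and 3 of 8 differences between 3', middle and 5' control probe sets separated the sides completely, too few to decide; no biological explanation of the split was tested.

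The third pattern is that GTO array 1 resembled the MS arrays, with a correlation of 0.943 with MS array 3, against 0.892 and 0.89 with GTO arrays 2 and 3. A share of MS neurons in that sample may be the reason. Of 33 probe sets at log2 8 or more on all MS arrays and under log2 4 on GTO arrays 2 and 3, 3 (9.09%, exact 95% interval 1.92 to 24.3) were under log2 4 on GTO array 1. Chosen in the same way by the other GTO arrays, 3 of 12 were under log2 4 on GTO array 2 and 3 of 3 on GTO array 3. These 3 are the same probe sets in each case, since they are under log2 4 on all 3 GTO arrays, so the shares differ only through the numbers chosen. Of the 33, 14 read between log2 4 and 8 and 16 at log2 8 or more on GTO array 1. Of the 12, 9 read at log2 8 or more on GTO array 2. Kept signal under this choice was thus most frequent on GTO array 1 and also occurred on GTO array 2. A mixture and a loss of signal on the other GTO arrays cannot be told apart by the share on GTO array 1, since both predict a low share.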

How the results depend on the processing

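Leaving out GTO arrays 2 and 3 and the block for the array split were chosen after the data had been seen. The 3 probe sets past the adjusted threshold, all on the deposited list, became 12 (9 of them listed) with no filter on low values, 11 (10 listed) with the filter at log2 6 and 11 (10 listed) with array weights. The same 3 passed under quantile normalization, while the 3 with the ordinary statistic held Pik3c3, 1 other listed probe set (2 listed in all) and 1 higher in GTO. The count was 0, listed probe sets included, with the replicate block, median centring, the floor at log2 4, the intensity trend, either added alternative (the first leaves 1 GTO array, assumed to vary like the MS arrays), and each array left out (0 to 0). The adjusted p of Pik3c3 ranged from 0.0069 to 0.521, that of Pcmtd1 from 0.0247 to 0.521 and that of Ctnna1 from 0.0254 to 0.521, while their log2 differences stayed between 5.31 and 7.36. The looser count, 1295, was 861 (699 higher in MS) with the ordinary statistic and 896 with the filter at log2 6, which tests fewer probe sets, and 796 to 1786 with 1 array left out (680 to 1500 higher in MS, 114 to 358 higher in GTO). Its 1053 against 242 became 700 against 638 under quantile normalization, 742 against 472 under median centring and 801 against 398 without GTO arrays 2 and 3. The rule of the deposited list, 626 against 63, gave 400 against 128, 429 against 125 and 376 against 519 in these settings, 468 against 54 with the floor, and 438 to 936 against 40 to 151 with 1 array left out. The filter at log2 6 left 379 listed probe sets, all higher in MS, because fewer were tested. In every alternative all listed probe sets tested were higher in MS (590 in all but the filter settings). Same-numbered MS and GTO arrays deviated together at r = -0.06, 0.10 and 0.11. GTO arrays 2 and 3 correlated best with the MS array of their own number, and GTO array 1 did not. With 3 arrays per group these values cannot decide whether the numbers pair the samples. Whether same-numbered pools share sorts was not given in the sources used here. The block moved the adjusted count from 3 to 0 and the looser count from 1295 to 1401. Of 838 values recomputed for 50 named probe sets under 17 alternatives, 781 kept their direction and side of the threshold, 38 no longer passed, 19 newly passed and 0 changed direction. Most of the 781 belong to probe sets that had not passed, since only 3 had. All were chosen for large differences, which favours an unchanged direction. The 38 losses all belong to the 3 called genes. Of the 17 alternatives, Pik3c3 passed in 5, Pcmtd1 in 4 and Ctnna1 in 4. The cause of the changes between settings was not tested except where fewer arrays or probe sets explain it. The tests of gene lists and all their alternatives, including the mean over probe sets, the estimated correlation and fry, were not run. Signal over background limits the folds of the 207 listed probe sets under log2 4 on all GTO arrays.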

Other observations

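The genes in this part were chosen after their values had been seen, and all come from the deposited list, so their shared direction follows from that selection. Adhesion and wiring molecules on the list included Ncam2, a neural cell adhesion molecule (11.03 ± 1.23 in MS and 7.66 ± 1.58 in GTO, log2, SD, n = 3), and Lrrc4c, a netrin-G ligand (10.62 ± 0.15 and 7.15 ± 1.90). The teneurins Tenm3 and Tenm4 had log2 differences of 3.29 and 2.68, and the contactin Cntn3 of 2.39, while the contactin Cntn2, under log2 4 on all GTO arrays, read at least 5.20-fold higher in MS. Dag1, dystroglycan, read 9.61 and 8.98 on MS arrays 1 and 2 but 4.83 on MS array 3, and 3.32 to 3.50 on the GTO arrays. Of the matrix receptor subunits, Itga1 read 4.40 and 4.17 on MS arrays 1 and 2, 7.86 on MS array 3 and 2.43 to 2.74 on the GTO arrays, and Itgb1 differed by 4.05, with Itgb1 at 6.43 on GTO array 1 and 3.69 and 3.71 on GTO arrays 2 and 3. None passed the adjusted threshold in limma (0.244 for Itgb1, 0.264 for Cntn3).

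Besides Ifi35, the list held interferon pathway genes: the receptor subunit Ifnar2, the transcription factor Stat2 and the antiviral kinase Eif2ak2. Ifnar2 had a log2 difference of 3.12, and Stat2 and Eif2ak2, under log2 4 on all GTO arrays, read at least 2.36-fold and 5.22-fold higher in MS (limma adjusted p = 0.223, 0.171 and 0.268). Genes that shape firing and transmitter release were Fgf14, a sodium channel regulator (log2 difference 3.02), Rims3, an active zone protein (2.37), the glutamate transporter Slc1a1 (3.56) and Kctd8, an auxiliary subunit of GABA receptors (2.57). With 1 array left out, the difference ranged from 2.08 to 3.86 for Fgf14 and 1.58 to 3.24 for Rims3. It ranged from 2.34 to 4.29 for Slc1a1 and 2.10 to 3.11 for Kctd8. The cannabinoid receptor gene Cnr1, under log2 4 on all GTO arrays, read at least 3.40-fold higher in MS. Kcnip2, a potassium channel partner, read 7.15 and 6.98 on MS arrays 1 and 2 but 3.66 on MS array 3, against 2.63 to 2.70 on the GTO arrays. None of these passed in limma either, and Kcnip2 did not pass the filter on low values.

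Polr2a, which all nuclei transcribing messenger RNA need, read 6.39 to 7.10 on the MS arrays and 2.58 to 2.96 on the GTO arrays with the listed probe set, close to the 1.86 to 2.89 of the bacterial background controls. Other probe sets for it were not analysed here, since the sources used gave no array annotation to name them.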
